A study of Populus deltoides with 38 samples.

How the data were processed

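The series holds leaf samples of Populus deltoides: 18 mRNA libraries, 18 small RNA libraries and 2 degradome pools. Per the labels, 72 plants raised from stem cuttings for 8 weeks were moved to hydroponics, received 0, 100 or 1500 µM sulfate for 12 days and then 0 or 50 µM CdCl2 with the same sulfate for 21 days. Groups and replicate numbers were taken from the sample titles, and each mRNA and small RNA group had 3 libraries. Per the labels, RNA had an integrity number above 7.0, libraries were read on Illumina instruments, and equal amounts of 9 RNAs were mixed for each degradome pool. Nothing in the labels says which plants each library came from, so p-values measure only the spread between these samples, which may be technical.

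For mRNA, the authors deposited FPKM values per locus, with a locus number, a Populus gene identifier and coordinates. The submitters' processing notes name TopHat2 2.1.1, and the genome build, the annotation and the program that computed FPKM are not given in the sources used here. FPKM values keep no library totals, so the mRNA depth is unknown. Among the 39572 loci, 638 had no gene identifier and 749 joined more than 1 identifier. A listed 0 can be a failed estimate: 107 loci were listed at 0 in 1 library while the other 2 libraries of the group exceeded 5 FPKM, and Potri.007G026200 was listed at 0 in 5 libraries and at 249.6 to 486.3 FPKM in the others.

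For small RNA, the authors deposited, for each mature sequence and hairpin, an expected count per library and a normalized signal. Per the file headers, reads were assigned to miRBase precursors and the genome, and the mapper and build are not given in the sources used here. The deposited expected counts are fractional where reads were split over hairpins. With 1 hairpin entry taken per mature sequence, also for sequences listed at more than 1 hairpin, 28.3% of values above 0 were not whole (tolerance 1e-06). The 1386 entries cover 1162 mature sequences, 533 with miRBase-type names and 629 named as predicted candidates, and 168 sequences are listed at more than 1 hairpin. After summing over hairpins 79.3% of values were whole within 0.01. The normalized signal deposited by the authors is the raw value times 1 factor per library, and it was not used for tests. Further, 11 entries without values were not used here.

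For the degradome, the authors deposited raw read counts at each cut site, a value divided over the transcripts a read matched, which is an estimated count, a scaled signal per the file headers (TPB), an alignment score from 0 to 4 in which lower is better, and a category from 0 to 4. TPB is named but not spelled out in the headers, and it equals the divided read count times 89.636 without Cd and 102.823 with Cd.

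Gene names were sought in a table of reference genes. Of the 39512 Populus identifiers 0 matched its names or tags, so none of the 33 gene lists fixed beforehand (among them sulfate assimilation, glutathione synthesis, metal transport, senescence and markers of other cell types) could be tested, and loci are given by identifier only. The 7 miRNA lists fixed beforehand (sulfur, copper, phosphate, auxin, growth and development, resistance genes, poplar) were matched by family number and tested.

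For mRNA, log2(FPKM + 1) of the 23166 loci with a mean of at least 1 over the 18 libraries was fitted with limma 3.58.1 (trend, robust empirical Bayes) in R 4.3.3, with 6 group means, 12 residual degrees of freedom and contrasts for each comparison. Log2 changes are on this scale, which understates the change of low loci. For small RNA, the expected counts were summed over hairpins, rounded to whole numbers and tested with edgeR 4.0.16 (TMM, filterByExpr on the groups, quasi-likelihood F test) on 368 sequences, with a common dispersion of 0.076, a biological coefficient of variation of 27.5%. CPM are edgeR's counts scaled by the TMM-adjusted library totals. Standard errors were taken as the log2 change over the square root of F. The interaction was an F test over the sulfate levels, and its printed value is the Cd effect at low minus that at middle sulfate. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and a feature was called at an adjusted p under 0.05. The lists of miRNAs were tested with camera (preset correlation of 0.01, and an estimated one) and fry from limma. Counts adjusted over the list alone use only the members of the list.

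The groups, tests, list members, naming rule and most alternatives were fixed before the data were examined. Chosen afterwards were the sums of reads by family with their alternatives, camera and fry on the miRNA lists, the largest single hairpin in place of the sum, leaving out loci with isolated zeros, the counts without libraries −CdH1 (mRNA) and +CdH3 (small RNA), the category 0 and 1 pairs, and the runs of target genes through the alternatives. A robust quasi-likelihood fit for small RNA was used in a first look and was replaced by the default after its counts had been seen, because the design fixed beforehand names no robust option for small RNA. Both are given among the alternatives. The naming rule took, for each averaged contrast, the called features of largest change with a mean of at least 5 FPKM, and, as no names could be had, at most 2 identifiers per direction. For small RNA it took each family of the sulfur, copper, phosphate and resistance-gene lists and the 5 sequences with the smallest p per direction, and for the interaction the smallest p values. Some were left out for length.

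Degradome pairs were counted as shared when the small RNA, transcript and position were the same. Intervals of single read counts are exact Poisson intervals at 95%, and they cover counting error only. Changes of miRNA families and of their listed targets were related by Spearman's rho and the share of opposite signs over 356 pairs of 67 families and 337 genes, with 100000 reassignments of families to targets.

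The alternatives were other scalings (DESeq2-type size factors and quantile normalization, which for small RNA was run on log2 CPM with limma, beside limma on log2 CPM with the TMM scaling, added later to part tool from scaling), another pseudocount of 0.1, no filter and a filter at 5, DESeq2 1.42.0 for small RNA, no robust step, a fit on only the groups compared, the replicate number as a block, each library left out in turn, and a 2-fold minimum. Correlations of deviations showed whether equal replicate numbers pair the samples, and they do not. For each comparison of groups the counts were also taken over other splits of the same libraries, up to 100.

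The limma and edgeR fits were tested on simulated data for 4 contrasts, of which low sulfate and the interaction were added after the results had been seen. Camera, fry, the sums by family and the reassignment of families to targets were not tested so. The mRNA runs changed 100 loci at each fold size, far fewer than were called in the same contrasts of the data, so their rates need not carry over. For the averaged Cd contrast in mRNA, run on 23166 loci, 95.0% of 2-fold and 75.0% of 1.5-fold simulated changes were recovered with 12 false calls. For Cd at middle sulfate 70.0% and 37.0% were recovered with 6 false calls. In small RNA, on 363 sequences, 91.9% of 2-fold and 100.0% of 4-fold changes were recovered with 3 false calls for the averaged contrast. At middle sulfate, on 355 sequences, 45.9% and 95.2% were recovered with 2 false calls. For low sulfate averaged over Cd, 93.0% of 2-fold and 65.0% of 1.5-fold changes were recovered in mRNA with 7 false calls, and 84.2% of 2-fold and 100.0% of 4-fold changes in small RNA, on 369 sequences, with 2 false calls. For the interaction 49.0% of 2-fold and 8.0% of 1.5-fold changes were recovered in mRNA with 3 false calls, and 13.5% of 2-fold and 54.2% of 4-fold changes in small RNA, on 362 sequences, with 0 false calls. Degradome and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.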

Results

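Leaves of the poplar Populus deltoides were profiled after a crossed sulfate and cadmium (Cd) treatment. Plants raised from stem cuttings received 0, 100 or 1500 µM sulfate (low, middle and high) for 12 days, and then either no Cd or 50 µM CdCl2 at the same sulfate for another 21 days. The series title concerns sulfur in the detoxification and accumulation of Cd in leaves. Each of the 6 groups had 3 mRNA libraries and 3 small RNA libraries. A degradome library, which records the cut ends of transcripts, was made from a pool of 9 RNAs at each Cd level. Libraries are named by Cd treatment, sulfate level and replicate number, so that +CdL1 is replicate 1 with Cd at low sulfate. Low and high sulfate were both compared with middle sulfate.

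The mRNA values were FPKM for 39572 loci, of which 23166 had a mean of at least 1 and were tested, and their read depth is unknown. The small RNA values were reads assigned to 1162 mature miRNA sequences, of which 368 had enough reads to test. Their totals ran from 498205 reads in +CdH3 to 2934278 reads in −CdM2, and they count the listed miRNAs, not whole libraries. Replicates of a group correlated at 0.955 to 0.978 across genes in mRNA and at 0.958 to 0.992 across sequences in small RNA. No pair of small RNA replicates matched within sampling noise, with a chi-square per degree of freedom of 15.5 to 287.9. In the principal components of the mRNA, library −CdH1 lay at 21.59 on the component on which the low sulfate libraries without Cd lay at 32.54 to 38.84.

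**Figure D1:**
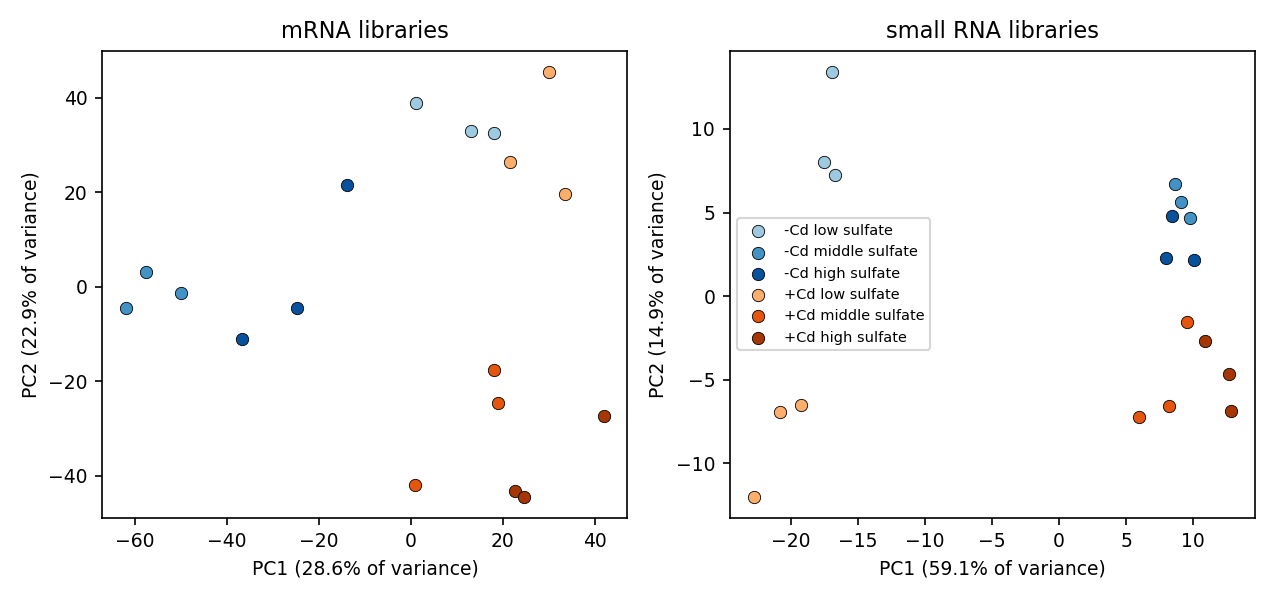
Principal components of the mRNA libraries (left) and small RNA libraries (right), with 1 point per library coloured by group and component scores on both axes. The horizontal and vertical axes hold 28.6% and 22.9% of the mRNA variance and 59.1% and 14.9% of the small RNA variance.

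The comparison of plants with and without Cd, averaged over sulfate, asked how leaves responded to the metal. The copper-responsive miRNAs rose together with Cd. This list, fixed beforehand, holds miR397, miR398, miR408, miR857 and miR1444, families known to respond to copper supply and to target transcripts of copper proteins such as laccases, copper/zinc superoxide dismutases, plantacyanin and polyphenol oxidases. All 14 of its tested sequences were higher, by a median of 1.94 on the log2 scale, and 14 also passed when adjusted over the list alone. The list moved apart from other sequences (limma camera, adjusted p = 3.3e-22, and adjusted p = 0.005 with an estimated correlation).

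Summed by family, miR408 reads rose by 2.52 ± 0.17 on the log2 scale (SE; edgeR, adjusted p = 1.4e-10) and were above the mean of the matching group without Cd in 9 of 9 libraries with Cd. At middle sulfate miR408 went from 2337 ± 219 CPM (reads scaled to library size) to 16350 ± 1700 (SD, n = 3). miR398 rose by 2.34 ± 0.18 (edgeR, adjusted p = 1.0e-09), miR397 by 1.89 ± 0.20 (edgeR, adjusted p = 1.1e-07) and miR1444 by 1.39 ± 0.15 (edgeR, adjusted p = 1.1e-07), each in 9 of 9 libraries. The single sequences with the smallest p were hbr-miR408a_R-1_1ss6TG (2.51 ± 0.17; edgeR, adjusted p = 1.4e-09), ptc-miR408-3p (2.53 ± 0.18; 1.6e-09) and ptc-miR398b (2.35 ± 0.19; 1.6e-08). The sequences PC-5p-3424_2762 (−1.13 ± 0.23; edgeR, adjusted p = 0.001), a predicted candidate, and sly-miR164a-5p_1ss21AT (−0.72 ± 0.16; 0.003) were lower with Cd. In all, 99 of 368 small RNAs changed, 49 higher and 50 lower (edgeR, Benjamini-Hochberg).

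**Figure D2:**
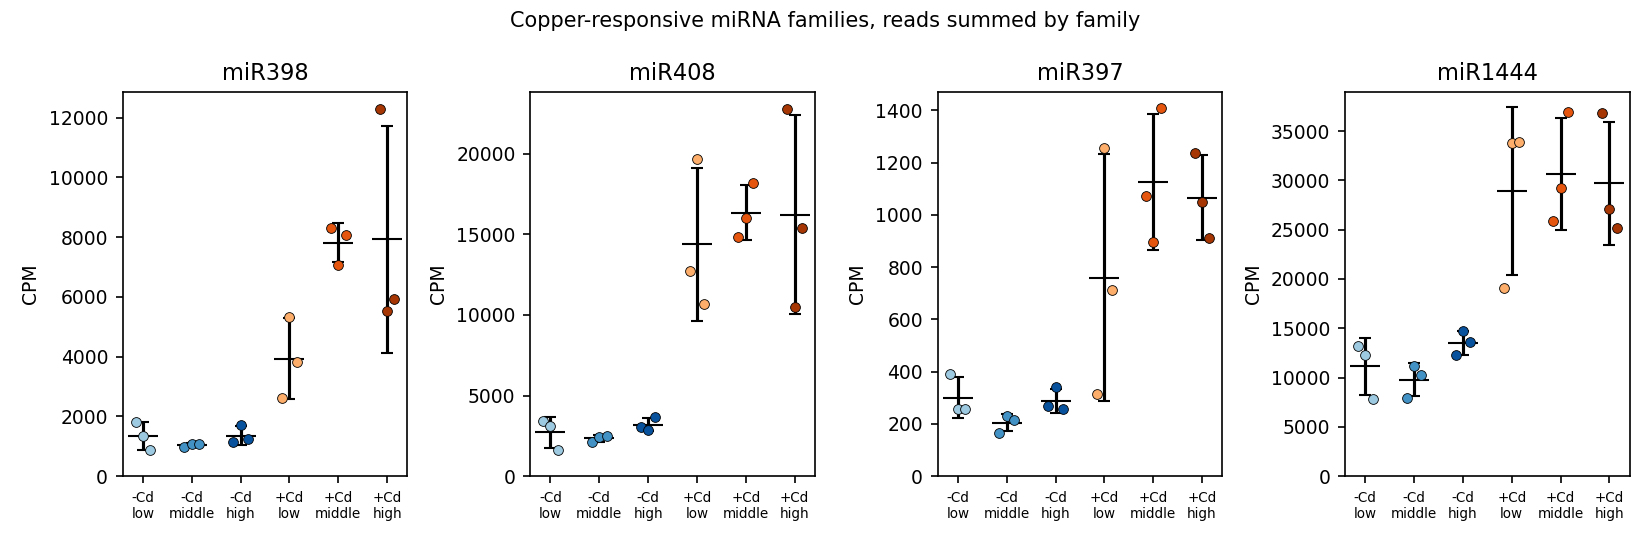
Reads of the copper-responsive families miR397, miR398, miR408 and miR1444 in CPM (vertical axis), with 1 point per library and horizontal lines and error bars for the mean and SD of the 3 libraries of each group (horizontal axis). The miR408 mean at middle sulfate was 2337 without Cd and 16350 with Cd.

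In mRNA, 6515 of 23166 loci (28.1%) changed with Cd, 2758 higher and 3757 lower (limma, Benjamini-Hochberg). Under quantile normalization 4133 were higher and 3046 lower, so the balance of directions rests on the scaling. With a change of at least 2-fold also asked for, 44 loci were higher and 491 lower. The files pair the Populus gene identifiers with no names, so loci are given by identifier and position as the files list them. Potri.003G138700 (chromosome 3, 15663752 to 15664535) rose by 1.63 ± 0.20 (limma, adjusted p = 4.0e-05), from 160.00 ± 53.41 to 779.89 ± 44.70 FPKM at middle sulfate (SD, n = 3), and was higher in 9 of 9 libraries. Potri.001G110700 (chromosome 1, 8795669 to 8796701) fell by 3.02 ± 0.17 on the log2 scale (limma, adjusted p = 1.4e-07), from 84.97 ± 3.43 to 5.26 ± 1.12 FPKM at middle sulfate, and was lower in 9 of 9 libraries. The naming rule also gave loci of larger change, Potri.002G188000 (3.15 ± 0.49; limma, adjusted p = 3.6e-04) and Potri.012G021600 (−3.86 ± 0.57; limma, adjusted p = 2.4e-04).

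Other miRNA lists moved less with Cd. Of 33 tested auxin-related sequences (miR160, miR167, miR390 and miR393), 1 was higher and 7 lower (adjusted over the list alone, 1 and 6; camera adjusted p = 0.282). Of 114 growth and development sequences, 13 were higher and 10 lower (adjusted over the list alone, 11 and 4; camera adjusted p = 0.485), and of 55 sequences of families described mainly in poplar, 15 were higher and 7 lower (16 and 10 adjusted over the list alone; camera adjusted p = 0.10). The 16 resistance-gene sequences of miR472, miR482 and miR1448, families known to target disease resistance transcripts, gave 1 higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.726). Quantile normalization gave 0 higher and 6 lower in the auxin list, 12 and 13 in the growth list and 1 and 3 in the resistance-gene list, and RLE size factors gave 12 and 5 in the growth list. The resistance-gene list holds miR472, at 275600 CPM in the middle sulfate group without Cd, whose sum changed by −0.02 (edgeR, adjusted p = 0.922). Of the 14 sulfur-list sequences 0 passed in edgeR, over all sequences or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 (median −0.30, camera adjusted p = 0.485). Under quantile normalization 1 was lower, and edgeR called 1 lower without −CdM2 or −CdH3 and 2 without −CdM3 or +CdL3. The miR395 sum passed, at −0.37 ± 0.13 (edgeR, adjusted p = 0.036) and lower in 7 of 9 libraries, but not under quantile normalization (−0.16; limma, adjusted p = 0.409). It passed with −CdM3, −CdH2, −CdH3, +CdL3, +CdH1 or +CdH3 left out, and not with any of the other 12 libraries left out (edgeR, adjusted p up to 0.177). In the phosphate list 3 of 20 sequences were lower (3 adjusted over the list alone; camera adjusted p = 0.010, and adjusted p = 0.603 with an estimated correlation), 7 under quantile normalization, 4 by DESeq2, and 1 to 6 with single libraries left out, lowest without −CdL3 and highest without +CdL2 or +CdM1. Without −CdL3 or +CdL1, 1 was higher.

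The Cd counts of the other lists also moved when single libraries were left out. The auxin list then gave 3 to 6 lower, lowest without −CdH1 or +CdM2, and 0 to 3 higher, highest without +CdL2. The growth list gave 2 to 10 lower, lowest without +CdM2, and 10 to 18 higher, highest without +CdL2. The poplar list gave 3 to 10 lower, highest without −CdM3 and lowest without −CdL3, −CdM2, −CdH3, +CdL1, +CdM2 or +CdH2. The resistance-gene list gave up to 4 higher, without +CdM3, and up to 3 lower, without +CdH1. By fry, the balance of direction passed for the copper list (limma, adjusted p = 1.9e-07) and not for the auxin (0.053), poplar (0.053), phosphate (0.135), sulfur (0.212), resistance-gene (0.457) or growth list (0.742). For change in either direction, fry also passed for the auxin (limma, adjusted p = 3.7e-05), growth (2.3e-08), poplar (9.0e-09) and resistance-gene lists (0.002). It did not for the phosphate (0.072) or sulfur list (0.202).

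The effect of Cd was then compared within each sulfate level, which asks whether sulfate supply altered the response. Cd changed many mRNAs at middle and high sulfate and few at low sulfate, whereas more small RNAs changed at low sulfate than at the other levels. At middle sulfate 4820 loci changed (20.8%; 1787 higher, 3033 lower), at high sulfate 3108 (13.4%; 1117 and 1991) and at low sulfate 166 (0.7%; 74 and 92), by limma with Benjamini-Hochberg adjustment. Under quantile normalization the middle sulfate split was 2958 higher and 2488 lower, and the high sulfate split 1706 and 1691. The copper families took part at each level, with miR408 changes of 2.41 at low, 2.81 at middle and 2.34 at high sulfate, and no interaction past the threshold (edgeR, adjusted p = 0.677). The interaction also missed the threshold for miR398 (0.118), miR397 (0.287) and miR1444 (0.605), by edgeR with Benjamini-Hochberg adjustment. It passed for miR398 without −CdL3 (−1.64; edgeR, adjusted p = 0.018) and for miR397 under quantile normalization (−1.56; limma, adjusted p = 0.041) and without +CdL2 (−1.65; edgeR, adjusted p = 0.048). At high sulfate the miR1444 change of 1.14 was not past the threshold under quantile normalization (0.37; limma, adjusted p = 0.329). The miR397 change of 1.34 at low sulfate was no longer past it without −CdL2 (1.14; edgeR, adjusted p = 0.061) or +CdL2 (0.81; adjusted p = 0.101).

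At middle and high sulfate the mRNA responses overlapped. Both levels called 537 loci higher, where independent lists would share 86.2, and 1512 lower, where they would share 260.7, and 4 loci went opposite ways. The loci higher with Cd at middle sulfate had a median change of 0.52 there, 0.31 at high and 0.10 at low sulfate, and those lower had medians of −0.65, −0.43 and −0.06. For the loci called at high sulfate the medians were 0.35 at middle, 0.50 at high and 0.10 at low sulfate (higher) and −0.68, −0.65 and −0.14 (lower). Loci picked by their call at a level tend to show a larger change there, so these medians do not rank middle against high sulfate. The interaction test called 988 loci (4.3%), and 786 of them had a Cd effect that lay higher at low than at middle sulfate. Among these 988, the Cd change was larger in size at middle than at low sulfate for 895, and 607 had opposite signs. Removing single libraries moved the low sulfate count to 60 without −CdL2, 62 without −CdL3, 93 without +CdL1, 110 without +CdL2 and 73 without +CdL3. It moved the middle count to 3205 without −CdM3, the high count to 1833 without −CdH1 and 1938 without +CdH2, and the interaction count to 531, 440, 608 and 520 without −CdL1, −CdL2, −CdM3 and +CdL1.

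Among the small RNAs, miR477 rose with Cd most at low sulfate, from 16.74 ± 6.48 to 483.3 ± 267 CPM (SD, n = 3), a log2 change of 4.81 ± 0.52 (edgeR, adjusted p = 6.9e-07). Its sum rose by 2.23 ± 0.47 at middle sulfate (edgeR, adjusted p = 0.003, but 1.49 and 0.059 without +CdM3) and changed by 0.10 at high sulfate (adjusted p = 0.933), and the interaction passed (adjusted p = 3.1e-04). miR1446 rose at low sulfate by 3.59 ± 0.46 (edgeR, adjusted p = 4.9e-06) and miR169, which targets subunits of the NF-Y transcription factor, by 2.29 ± 0.35 (4.0e-05). Their interactions passed, with low minus middle differences in the Cd effect of 2.1 ± 0.6 and 1.52 ± 0.47 (edgeR, adjusted p = 0.001 and 0.005), and in limma with the TMM scaling (0.002 and 0.004), but not under quantile normalization (limma, 0.128 and 0.069). There the differences kept their size, at 1.99 ± 0.88 and 1.59 ± 0.63, and the calls ended with the larger standard errors. miR6462 fell by 1.72 ± 0.24 on the log2 scale at low sulfate, from 944.4 ± 174 to 286.4 ± 81.7 CPM (edgeR, adjusted p = 1.2e-05), with changes of 0.24 at middle and 0.48 at high sulfate and an interaction past the threshold (2.2e-04). Cd changed 63 small RNAs at low sulfate (42 higher, 21 lower), 30 at middle (24 and 6) and 25 at high (15 and 10), and the interaction called 22 (edgeR, Benjamini-Hochberg). DESeq2 gave 43 higher and 33 lower at low sulfate. Under quantile normalization the splits were 37 and 39 at low and 16 and 10 at middle sulfate, and the median change over all sequences went from −0.032 to −0.159 at low and from −0.110 to 0.012 at high sulfate. RLE size factors gave medians of −0.078 and −0.040, and limma with the TMM scaling −0.055 and −0.114, with 41 higher and 28 lower at low sulfate, so most of the shift came with the quantile step.

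Several of these small RNA counts rested on single libraries. The middle sulfate count became 17, 15 and 16 without −CdM1, −CdM2 and +CdM3. The high sulfate count became 15, 12, 8, 16 and 13 without −CdH1, −CdH2, −CdH3, +CdH2 and +CdH3. The interaction count became 9, 13, 10, 9, 12 and 14 without −CdL1, −CdL2, −CdH2, +CdL3, +CdH2 and +CdH3.

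**Figure D3:**
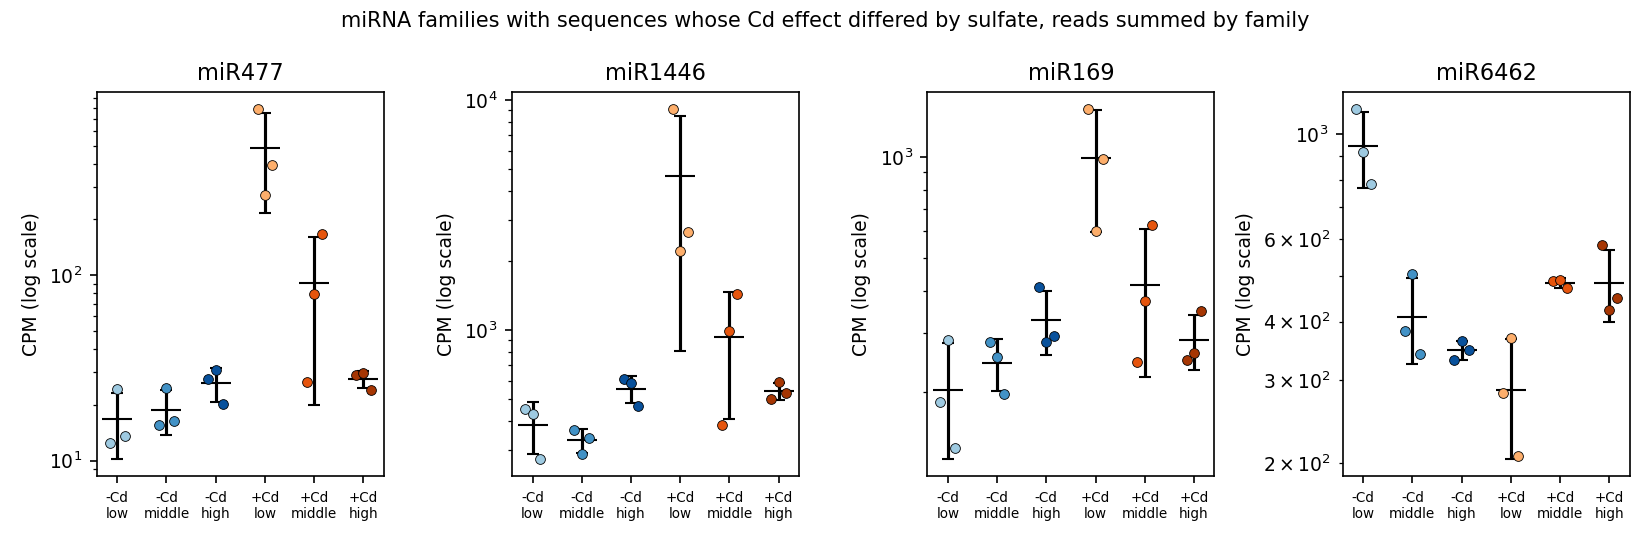
Reads of miR477, miR1446, miR169 and miR6462 in CPM (vertical axis, log scale), with 1 point per library and the mean and SD of the 3 libraries of each group (horizontal axis). At low sulfate the miR477 mean was 16.74 without Cd and 483.3 with Cd, and at high sulfate 26.08 and 27.56.

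The comparison of low with middle sulfate asked what sulfate shortage did to the leaves. miR395, the family known to be induced by sulfate shortage and to target ATP sulfurylases and a sulfate transporter, rose by more than any other family tested. Its summed reads went from 300.7 ± 34.9 to 77930 ± 2660 CPM without Cd and from 355.0 ± 53.0 to 40760 ± 8820 CPM with Cd (SD, n = 3). Averaged over Cd this was a rise of 7.43 ± 0.21 on the log2 scale (edgeR, adjusted p = 1.5e-18), in 6 of 6 low sulfate libraries. In the low sulfate libraries miR395 made up 2.912% to 7.210% of the listed reads, and in the other libraries 0.014% to 0.037%. All 14 sequences of the sulfur list were higher (14 adjusted over the list alone), by a median of 7.94 (camera adjusted p = 7.4e-31, and adjusted p = 4.6e-06 with an estimated correlation; fry adjusted p = 1.8e-14). The smallest p among them was that of ptc-miR395b, at 8.11 ± 0.27 (edgeR, adjusted p = 1.8e-15). At low sulfate the miR395 sum was lower with than without Cd by −0.94 ± 0.23 (edgeR, adjusted p = 0.005), but not under quantile normalization (−0.16; limma, adjusted p = 0.800), and the interaction missed the threshold (−1.17, adjusted p = 0.077), but passed with RLE size factors (−1.26, adjusted p = 0.043) and without −CdL3 (0.043), −CdH1 (0.040), +CdM2 (0.045) or +CdH3 (0.033).

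The phosphate-responsive list moved the opposite way. Of its 20 tested sequences, 18 were lower at low sulfate and none higher (18 adjusted over the list alone), with a median of −2.04 (camera adjusted p = 8.8e-17, and adjusted p = 0.039 with an estimated correlation; fry adjusted p = 4.8e-05). miR399, known to be induced by phosphate shortage and to target the ubiquitin-conjugating enzyme PHO2, fell by 2.14 ± 0.25 on the log2 scale (edgeR, adjusted p = 1.8e-06). Without Cd it went from 14830 ± 824 CPM at middle to 4247 ± 1800 at low sulfate, and 6 of 6 low sulfate libraries were lower. miR827 fell by 1.56 ± 0.31 on the log2 scale (edgeR, adjusted p = 0.001), again in 6 of 6 libraries, while miR2111 changed by −0.09 (adjusted p = 0.777). The sequence with the smallest p among those lower was ptc-miR399a (−2.84 ± 0.31; edgeR, adjusted p = 3.8e-07).

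**Figure D4:**
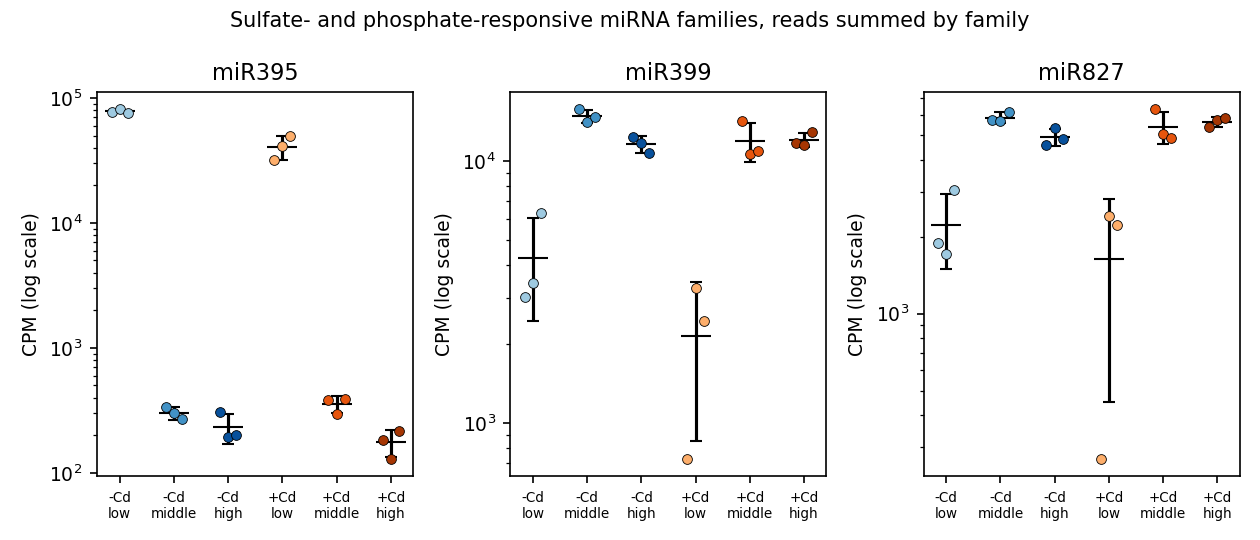
Reads of the sulfur family miR395 and the phosphate families miR399 and miR827 in CPM (vertical axis, log scale), with 1 point per library and the mean and SD of the 3 libraries of each group (horizontal axis). Without Cd the miR395 mean was 77930 at low and 300.7 at middle sulfate, and the miR399 mean 4247 and 14830.

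Of the 9 tested genes whose transcripts the degradome tables list as cut by miR395, 5 were lower and 1 higher at low sulfate and 3 did not pass (limma), with a median of −0.30, and the 3 genes of the strongest categories were all lower. Potri.010G081200 fell by 1.68 ± 0.09 on the log2 scale (limma, adjusted p = 2.2e-08) and Potri.008G159000 fell by 1.24 ± 0.18 (limma, adjusted p = 2.2e-04), each in 6 of 6 low sulfate libraries. They and other targets were singled out after their values had been seen, and near-identical copies can share their reads. Potri.010G081200 rose with Cd by 0.51 ± 0.07 (limma, adjusted p = 1.0e-04) in 9 of 9 libraries. Potri.006G099000 (chromosome 6, 7613290 to 7617918), picked by the size of its rise at low sulfate, stood at 35.9, 5.80 and 6.45 FPKM without Cd and 44.6, 49.2 and 33.9 FPKM with Cd at low sulfate, and was listed at 0 in the other 12 libraries.

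Averaged over Cd, 6198 mRNA loci (26.8%) changed at low sulfate, 2819 higher and 3379 lower, and under quantile normalization 4237 were higher and 2749 lower (limma, Benjamini-Hochberg). Without Cd the counts were 1165 higher and 2200 lower (quantile, 2655 and 1887), and with Cd 2158 and 1941. Both Cd levels called 216 loci higher and 599 lower, and 67 went opposite ways. The count without Cd of 3365 became 2218, 2035 and 1852 when −CdL1, −CdL2 and −CdM3 were left out, and the count with Cd of 4099 became 2282 and 2384 without +CdL1 and +CdM1. Of the small RNAs 83 changed, 52 higher and 31 lower (edgeR), against 32 and 63 under quantile normalization, where the median change over all sequences was −0.140 in place of 0.097. With limma and the TMM scaling 54 were higher and 32 lower (median 0.081), and RLE size factors gave a median of 0.038. miR395, miR399 and miR827 kept their directions and their calls under quantile normalization.

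In the remaining lists no camera test passed at low sulfate, while single sequences were called in some. Over all 368 sequences 83 were called (22.6%), and the growth list had 114 tested, the poplar list 55 and the auxin list 33. In the auxin list 3 sequences were higher and 1 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.944), and in the growth list 9 and 9 (7 and 7 adjusted over the list alone; camera adjusted p = 0.053). The poplar list gave 10 higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.233), and the copper list 1 higher (1 adjusted over the list alone; camera adjusted p = 0.944). In the resistance-gene list 0 of 16 passed in edgeR, over all sequences or adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.944). Under quantile normalization the auxin list gave 0 higher and 4 lower, the growth list 3 and 22, the poplar list 5 and 7, the copper list 1 and 1 and the resistance-gene list 2 and 1. RLE size factors gave 3 and 2 in the auxin, 7 and 12 in the growth and 9 and 2 in the poplar list, and limma with the TMM scaling 3 and 2, 8 and 9, and 13 and 1. In edgeR and limma with the TMM scaling and with RLE size factors, the auxin and poplar lists thus had more higher than lower calls, but not after the quantile step. By fry the poplar list passed upward (limma, adjusted p = 0.003) and the auxin (0.467), growth (0.561), resistance-gene (0.592) and copper lists (0.666) did not. For change in either direction, fry passed for the auxin (limma, adjusted p = 1.2e-06), growth (4.3e-08) and poplar lists (4.6e-07). It did not for the copper (0.177) or resistance-gene list (0.211). With single libraries left out the poplar list gave 3 to 17 higher, without −CdL3 and −CdM2, the growth list 4 to 8 higher, lowest without +CdM2, and 4 to 11 lower, lowest without −CdM1 or +CdL3. The auxin list gave 1 to 5 higher, without −CdM1 and −CdM2, the copper list 2 higher without +CdL1 and the resistance-gene list 1 lower without +CdL1.

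Few small RNAs or mRNA loci passed the threshold between high and middle sulfate. The sulfur list lay at a median of −0.83, or −0.42 under quantile normalization (camera adjusted p = 8.8e-07, and adjusted p = 0.014 with an estimated correlation; fry adjusted p = 0.037), with 0 of 14 sequences past the threshold in edgeR (7 at an unadjusted p under 0.05, 1 by DESeq2) and 5 lower when adjusted over the list alone. The miR395 sum changed by −0.69 ± 0.16 (edgeR, adjusted p = 0.051), lower in 5 of 6 high sulfate libraries, but it passed without −CdH1 (−0.82, adjusted p = 0.008), +CdM2 (−0.73, 0.042) or +CdH3 (−0.77, 0.013). Over all sequences 0 small RNAs passed in edgeR (12 at an unadjusted p under 0.05), and DESeq2 called 1, while edgeR gave 1 without −CdH1 and 1 without +CdM2. The copper list lay at 0.21 (camera adjusted p = 0.003, and adjusted p = 0.304 with an estimated correlation), the phosphate list at −0.34 (1.5e-04 and 0.304) and the resistance-gene list had camera adjusted p = 0.017, and adjusted p = 0.304 with an estimated correlation. The auxin, growth and poplar lists gave camera adjusted p = 0.656, 0.077 and 0.734. In each of these 6 lists 0 sequences passed in edgeR, over all sequences or adjusted over the list alone, and 0 by DESeq2, with 0 at an unadjusted p under 0.05 except 3 of the growth and 1 of the resistance-gene list. By fry none of these 6 lists passed, with adjusted p from 0.483 to 0.998.

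The 431 mRNA loci called at high sulfate averaged over Cd, 53 higher and 378 lower (limma, Benjamini-Hochberg), were not stable. Quantile normalization gave 53 higher and 130 lower. Leaving out −CdM2, −CdM3, −CdH1, −CdH2, +CdM3 or +CdH3 gave 2, 1, 3, 2, 1 and 2 loci, and leaving out −CdM1, +CdM1 or +CdH2 gave 673, 94 and 201. Without Cd 19 loci were called, 8 higher and 11 lower (quantile, 14 and 9; DESeq2-type size factors, 7 and 6), and leaving out −CdM1, −CdM2, −CdM3, −CdH1, −CdH2 or −CdH3 gave 170, 2, 0, 1, 1 and 213. With Cd limma called 0 loci, with 1925 at an unadjusted p under 0.05, 0 under size factors and under quantile normalization, and 5 without +CdM1. More loci had an unadjusted p under 0.05 in limma averaged over Cd (3379 of 23166) and without Cd (3568), so smaller differences below the threshold stay possible. No locus is named for this comparison, since the calls of those that the naming rule gave each ended when some single library was left out.

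The degradome asked which transcripts the miRNAs cut. The authors' tables list 5250 pairs of a small RNA and a cut site in 855 genes for 83 families, with 4074 in the pool without Cd, 3762 in the pool with Cd and 2586 (49.3%) in both. Of the 2 strongest categories, in which the cut site holds or shares the highest read count on its transcript, 1238 and 1310 pairs were listed and 1086 in both. A miR1444 target, Potri.001G388900, had 6061 reads at its site without Cd (95% Poisson interval 5909.4 to 6215.5) and 6445 with Cd (6288.6 to 6604.3). The miR395 target Potri.010G081200 had 48 (35.4 to 63.6) and 75 (59.0 to 94.0) reads. Each pool is a single library without replicates, so the values compare 2 libraries and not 2 treatments.

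Target transcripts of some families moved against their miRNA, and those of others did not. Potri.001G388900 fell by 1.09 ± 0.11 on the log2 scale with Cd (limma, adjusted p = 7.2e-06) in 9 of 9 libraries, and of the 5 tested miR1444 targets of the strongest categories 3 fell (of all 7 tested, 4 fell and 1 rose). At low sulfate, however, 3 of these 5 were lower and 1 higher, and Potri.001G388900 was lower in 6 of 6 libraries. The miR1444 sum changed there by only 0.05 (edgeR, adjusted p = 0.850). All 3 miR395 targets of those categories fell at low sulfate, although the smallest, Potri.002G092400 (−0.42; limma, adjusted p = 0.023), missed the threshold under quantile normalization (0.057) and without −CdM1 (0.052), +CdL3 (0.053), +CdM2 (0.054) or +CdM3 (0.055). Both tested miR827 targets rose at low sulfate, where miR827 fell, whereas the 2 tested miR399 targets of the strongest categories fell with miR399 (median −0.57), and of all 22 tested miR399 targets 4 rose and 3 fell. With Cd the 6 tested targets of miR397 had a median change of 0.05 and the 4 of miR408 one of −0.28, with 1 lower (limma), and those of the strongest categories, 5 and 3, had medians of 0.04 and −0.11. Over all 356 pairs of a family and a target gene, the share of opposite changes did not differ past the threshold from that with families reassigned at random. Spearman's rho across pairs, which are not independent replicates, was −0.11 for Cd (permutation p = 0.286, adjusted 0.429), −0.03 for low sulfate (0.696, adjusted 0.696) and 0.14 for high sulfate (0.183, adjusted 0.429), in 3 two-sided permutation tests. Signs were opposite for 54.5%, 47.2% and 48.6% of pairs, against 48.9%, 50.2% and 49.8% on average over 100000 reassignments (permutation p = 0.185, 0.423 and 0.775, unadjusted).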

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

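The counts over other splits of the libraries, the tests of the mRNA response at low sulfate, the signs of the 22 small RNAs and the family sum of miR399 were chosen after the results they address had been seen. For the tests of the 6 small RNAs and that of miR399 without miR395, the predictions were written before their outcomes were seen. The patterns that these tests address were still results of the same data.

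The effect of Cd differed between sulfate levels for 988 mRNA loci (limma) and 22 small RNAs (edgeR) in the interaction test. Of the loci with the smallest p, Potri.005G154300 had a Cd effect of 0.79 at low, −1.87 at middle and −1.68 at high sulfate, a low minus middle difference of 2.66 (limma, adjusted p = 4.2e-05). For Potri.013G143300 these were 0.99, −1.54 and −1.31, a difference of 2.53 (limma, adjusted p = 7.8e-04). Potri.016G068200 had effects of −1.15, 0.42 and 0.05, a difference of −1.58 (limma, adjusted p = 0.002), and Potri.011G150800 had −0.19, 1.23 and 0.61, a difference of −1.42 (limma, adjusted p = 0.003).

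The 6 small RNAs of smallest interaction p had Cd effects unlike each other. ptc-miR171l-5p_1ss1TC changed with Cd by 3.71 at low, 0.52 at middle and −0.95 at high sulfate, a low minus middle difference of 3.19 (edgeR, adjusted p = 5.0e-04). ptc-miR477a-5p changed by 5.38, 2.36 and 0.18, a difference of 3.02 (edgeR, adjusted p = 7.3e-04), ptc-MIR1446d-p3 by 4.12, 1.59 and −0.54, a difference of 2.53 (6.4e-04), and ptc-miR1446a_R+1 by 3.56, 1.48 and −0.01, a difference of 2.08 (0.006). Against these, ptc-MIR6462a-p3_1ss17GA changed by −1.82, 0.26 and 0.59, a difference of −2.08 (edgeR, adjusted p = 6.6e-04), and ptc-miR3627b by −1.50, 0.60 and 0.90, a difference of −2.11 (0.006). One scaling factor per library as the whole cause was argued against by the signs over all 22 called sequences, since 17 had a low minus middle difference above 0 and 5 below, while a factor moves all sequences of a library alike. Scaling of other kinds stays open. The 6 stayed called under both RLE size factors and quantile normalization, and whichever library of the low sulfate group with Cd was left out, but they had been picked for their small p, so this decides nothing. Of all 22, 21 stayed called under RLE size factors, 18 under quantile normalization, and 17, 21 and 9 without +CdL1, +CdL2 and +CdL3. Their differences then had a median of 0.96, 1.08 and 0.98 times the full size, and the lowest was 0.50 times. A single library thus stays open too, since sequences called over all libraries were chosen for agreeing ones. A differing response to Cd by sulfate supply may be among the explanations, next to differences between library batches, which the labels do not give.

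Cd changed 166 mRNA loci at low sulfate against 4820 at middle and 3108 at high sulfate. A larger spread between the low sulfate libraries was argued against by a ratio of 0.89 in the median SD of low over other groups. The fit behind these counts shares a single estimate of the spread over all groups, so such a spread could hardly act on them. Fits on only the groups compared, each with its own spread, gave 47, 3197 and 1282 loci at low, middle and high sulfate. A single library hiding the effect was argued against, since leaving out each low sulfate library gave at most 140 loci. That low sulfate alone may move loci the way Cd does stays open: 63.5% of the loci called for Cd at high sulfate had the same sign for low sulfate without Cd, but another of the 10 splits of those libraries gave 71.9%. These comparisons, which share no libraries, both called 116 loci higher and 771 lower, where independent lists would share 56.2 and 189.1. Opposite calls numbered 135, where independent lists would give 206.2. Loci are not independent of each other, so these overlaps are no test. A dependence of the response on sulfate supply, which the design names, was not separated from such a move by low sulfate alone.

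miR399 sequences were lower at low sulfate, where miR395 took up to 7.210% of the listed reads. That miR395 reads crowd out others was argued against by a median of −2.17 over the tested miR399 sequences with miR395 left out of counts and totals. Reads shared among miR399 sequences stay open: the family sum changed by −2.14, but with 16 of 16 tested sequences lower it had to fall, so this does not tell which of them fell by themselves. A response of miR399 to sulfate supply may be among the explanations, and the phosphate status of the leaves was not measured here.

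Chance as the source of the counts was examined by regrouping the same libraries, the real grouping included. Of 100 splits, 1 (the real one) gave as many mRNA calls for Cd averaged over sulfate (6515, highest other 4964), low sulfate (6198, highest other 1043), high sulfate (431, highest other 194) and the interaction (988, highest other 47). For small RNA 1 of 100 splits did so for Cd averaged (99, highest other 67), low sulfate (83, highest other 75) and the interaction (22, highest other 13), a share under 0.05. For the Cd, low sulfate and high sulfate counts, as fitted on all libraries, this argues against a random grouping of these libraries. A share of 1 in 100 is the smallest that 100 splits can give, and it was not adjusted over the contrasts. Regrouping cannot tell the treatments from other differences between the same libraries. For the interaction counts regrouping decides nothing, since their splits mixed the libraries of all groups. Such mixing adds the Cd and sulfate effects to the spread within groups, which lowers the other counts with or without an interaction. The other splits were not refitted with a library left out or under other settings, so for counts from such fits chance was not examined. Some of them were much lower. The 431 loci fell to 183 (quantile), 107 (replicate block), 94 without +CdM1 and 1 to 3 without −CdM2, −CdM3, −CdH1, −CdH2, +CdM3 or +CdH3. The 22 small RNAs of the interaction fell to 12 with the block and to 9, 13, 10, 9 and 12 without −CdL1, −CdL2, −CdH2, +CdL3 and +CdH2, and the 83 at low sulfate to as few as 59 with a single library left out. The 0 small RNAs at high sulfate (12 at an unadjusted p under 0.05 in edgeR, 1 by DESeq2) were matched by 100 of 100 splits, with 2 in the highest other, which says nothing about chance because every count is at least 0.

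Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. For mRNA the real counts and the highest others were 166 and 1 (Cd at low sulfate), 4820 and 1 (middle), 3108 and 0 (high), 3365 and 0 (low sulfate without Cd), 19 and 1 (high sulfate without Cd) and 4099 and 0 (low sulfate with Cd). For small RNA they were 63 and 1, 30 and 0, and 25 and 0 for Cd at low, middle and high sulfate. High sulfate with Cd gave 0 loci by limma (1925 at an unadjusted p under 0.05, and 0 under size factors or quantile normalization), and 10 of 10 splits gave as many, which a real count of 0 makes certain. Another grouping of those 6 libraries, the highest of the 10, gave 577 loci, so they may differ along some division other than sulfate. With so few splits chance is not excluded for that either, and what the division would be was not tested.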

How the results depend on the processing

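Of 174 recomputed counts of calls that left no library out, 148 stayed within 1.5 times the reported count, and tests on family sums, target genes, a robust small RNA fit, single hairpins and isolated zeros were chosen after the results had been seen. Where a count moved, the cause was not tested, except that a 2-fold minimum lowers a count by construction. Named mRNA results kept their call in 383 of such recomputations and lost it in 25, named small RNA sequences kept it in 218 and lost it in 0, and family sums kept their side of the threshold in 492, lost the call in 25 and gained it in 8. With single libraries left out, named mRNA results kept their call in 404 and lost it in 82, named small RNA sequences lost it in 0, and family sums kept their side in 1859, lost the call in 65 and gained it in 26. The named small RNA sequences were picked for the smallest p in these same data, so their keeping the call was nearly assured. Most named mRNA loci were picked for the size of their change, so these tallies do not compare the assays. The mRNA count for high sulfate averaged over Cd fell from 431 to 183 (quantile), 205 (no filter), 213 (only the groups compared), 107 (replicate block) and 76 (2-fold), and high sulfate without Cd from 19 to 10 (pseudocount 0.1), 1 (only the groups compared) and 7 (2-fold). Fits on only the groups compared gave 47, 3197 and 1282 loci for Cd at low, middle and high sulfate and 1675 for low sulfate with Cd. The 2-fold minimum left 535, 72, 1060 and 704 loci for Cd averaged and at low, middle and high sulfate, 732, 1221 and 541 for low sulfate averaged, without and with Cd, and 43 and 53 small RNAs for Cd and low sulfate averaged. In small RNA, high sulfate went from 0 calls (edgeR, 12 at an unadjusted p under 0.05) to 4 (no filter) and 1 (DESeq2), and the interaction from 22 to 40 (no filter).

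The replicate number was tried as a block, although equal numbers did not pair the samples (mean correlation of deviations −0.011 in mRNA and −0.019 in small RNA; 6 and 5 of 18 libraries matched best with their own number). The block gave 12 small RNAs for the interaction, 13 for Cd at high sulfate and 107 loci for high sulfate averaged over Cd, and moved no other count of calls by more than 1.5 times. Degradome pairs listed in both pools numbered 1086 with categories 0 and 1 only and 1149 by family and transcript, against 2586. The rho of miRNA and target changes for high sulfate was reversed with category 0 and 1 pairs, at −0.06 against 0.14, neither past a threshold.

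With each library left out in turn, mRNA counts ranged from 5522 to 6507 (Cd averaged), 60 to 140 (low), 3205 to 4276 (middle), 1833 to 2519 (high), 4833 to 6368 (low sulfate averaged), 1852 to 2996 (without Cd), 2282 to 3950 (with Cd), 1 to 673 (high sulfate averaged), 0 to 213 (without Cd), 0 to 5 (with Cd) and 440 to 1015 (interaction). The small RNA counts ranged from 71 to 109 (Cd averaged), 57 to 74 (low), 15 to 32 (middle), 8 to 36 (high), 59 to 92 (low sulfate), 0 to 1 (high sulfate) and 9 to 27 (interaction), where a lone pair of libraries in a group is assumed to vary like the others. Alternatives of the gene lists were not run, since no list was matched, fits on only the groups compared do not apply to the averaged Cd effect and the interaction, and pairs of called miRNAs could not be formed for high sulfate. Small RNA totals down to 498205 reads limit what low sequences can show, and mRNA depth is unknown.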

Other observations

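All family sums given here were tested after the data had been seen. In the growth list, miR530 fell with Cd by 0.63 ± 0.17 on the log2 scale (edgeR, adjusted p = 0.008; lower in 9 of 9 libraries), and it kept its call under each scaling and with each library left out. In the poplar list, miR481 fell by 0.62 ± 0.18 on the log2 scale (edgeR, adjusted p = 0.011; lower in 8 of 9 libraries). miR6424, miR6478 and miR7841, of the same list, rose with Cd by 0.73 ± 0.13 (edgeR, adjusted p = 2.6e-04), 0.77 ± 0.15 (7.8e-04) and 0.59 ± 0.14 (0.004), each in 9 of 9 libraries. miR6478 was also higher at low sulfate by 1.02 ± 0.19 (edgeR, adjusted p = 7.9e-04), in 6 of 6 libraries. Other family changes passed under the TMM scaling in edgeR and not under quantile normalization in limma: with Cd miR473 (0.74 and 0.39; adjusted p = 1.5e-04 and 0.065), miR156 (0.50 and 0.04; 0.026 and 0.868; also not without −CdM3, 0.067, or −CdH2, 0.075) and miR394 (0.60 and 0.14; 0.009 and 0.510), and at low sulfate miR6427 (0.67 and 0.27; 0.003 and 0.296). The miR169 call with Cd was likewise lost under quantile normalization (0.66; limma, adjusted p = 0.058). At low sulfate so were those of miR477 (0.99; limma, adjusted p = 0.125), miR1446 (0.77; 0.269), miR156 (−0.52; 0.148) and miR394 (−0.48; 0.070).

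Target transcripts of the strongest degradome categories also moved where the miRNA family sum did not pass the test. With Cd, 5 of 7 tested targets of miR472 and 4 of 7 of miR482 were lower (limma; 8 of 11 and 17 of 34 over all listed targets), while the sums of miR472 and miR482 changed by −0.02 and −0.16 (edgeR, adjusted p = 0.922 and 0.320). For miR530, which fell with Cd, 6 of 6 tested targets of these categories were lower too (limma), and of all 12 tested 8 were lower, 1 was higher and 3 did not pass. The median changes of the targets of these categories were small, at −0.24 (miR472), −0.30 (miR482) and −0.30 (miR530). These targets were not run under other scalings, and quantile normalization changed the balance of directions with Cd over all loci. Predicted candidates made up 0.224% to 0.528% of the listed small RNA reads in each library.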
